A study of Homo sapiens with 11 samples.

How the data were processed

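The samples were 11 poly(A) RNA libraries from the pancreatic cancer lines AsPC-1 and PANC-1, either controls or cells taken 48 hours after transfection of siRNA against MYEOV. Per the labels' protocols, libraries were sequenced as paired reads of 150 bases on an Illumina HiSeq. HISAT2, HTSeq and the human build hg19 are named in the submitters' processing notes, which give no versions. The authors deposited whole-number counts of reads per gene, with no normalization, 1 table per library. Each table lists 58735 Ensembl gene identifiers, and all 58735 occur in GENCODE release 29 (Ensembl 94, GRCh38), which was used for gene names and positions. Because the notes name hg19 and the identifiers match a GRCh38 annotation, positions are those of the GRCh38 annotation and no coordinate came from the deposited tables. The strand setting of the counting is not given in the sources used here. The tables held 0 rows without a gene name, so no share of unassigned reads could be computed.

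Groups were taken from the sample titles: AsPC-1 control (n = 2), AsPC-1 MYEOV siRNA (n = 3), PANC-1 control (n = 3) and PANC-1 MYEOV siRNA (n = 3). Totals ran from 12113093 to 15066456 counts per library, and from 22050 to 24025 genes were detected. Every pair of replicates of a group differed by more than Poisson sampling noise in a chi-square test over genes, so no library was treated as a duplicate.

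Each line was fitted on its own libraries with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 2.77% in AsPC-1 and 6.08% in PANC-1. The standard error of a log2 fold change was derived as its absolute value divided by the square root of the F statistic. The difference in response between lines was tested in 1 edgeR fit over all 4 groups. CPM values are counts scaled to library size with TMM factors, computed here from the deposited counts.

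Before the data were examined, 29 gene lists with 599 gene symbols were fixed: SOX9 and Notch pathway, serine and folate enzymes, MYC-driven ribosome biogenesis, cholesterol, glycolysis and hypoxia, ATF4 targets, endoplasmic reticulum chaperones, p53 targets, G1/S, G2/M, mesenchymal, epithelial, YAP/TEAD targets, TGF-beta response, interferon, NF-kB, ERK output, invasion and matrix, pancreatic lineage, apoptosis, RNA interference machinery, neighbours of MYEOV at 11q13, markers of fibroblasts, leukocytes and endothelium, and mitochondrial, histone, non-polyadenylated and ribosomal protein RNAs. All symbols matched a gene. Lists with at least 5 tested members were tested with camera (limma 3.58.1, voom values, preset correlation 0.01), and again with an estimated correlation and with fry. Member counts come from the edgeR fits.

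The genes named were chosen by a rule fixed at the same time. It took MYEOV, SOX9 and HES1; the 6 largest rises and 6 largest falls per line among called genes with a mean log2 CPM of at least 3 and no overlap between the groups' libraries; up to 2 members of each list called by camera and 1 of every other list; the 6 rises and 6 falls called in both lines whose smaller change was largest; and the 6 largest differences between lines. Some genes that the rule takes are not reported here. Further list members, such as DUSP6, SPRY2, CCND1, MKI67, ANLN, NDRG1, JAG1, CXCL1, AGO2, PRKRA and the MCM genes, were named after their values were seen.

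Alternatives were RLE and upper-quartile scaling, no low-count filter, a stricter filter of 5 CPM, DESeq2 1.42.0, 1 fit over all groups, the replicate number as a block, the other list tests and leaving out each library in turn. A restriction to genes without a 6-base word in the 3' UTR was added after seeing the data. Words of 7 bases in 3' UTRs (all 16384, those with at least 50 carriers tested) were compared with fold changes by a rank z statistic, against 100 permutations of fold changes over genes, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

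The fits were tested on simulated counts with known changes. The changed genes were drawn from those with a mean log2 CPM above 3. Each gene was given the dispersion of the trend over expression level, without a spread of its own, so recovery among all tested genes may be lower. For AsPC-1, 68.7%, 98.5% and 100% of genes changed by 0.3, 0.6 and 1.2 on the log2 scale were recovered among 14087 genes, with 10 false calls. For PANC-1 the shares were 40.3%, 95.5% and 100% among 14773 genes, with 5 false calls, and for the difference between lines 93.5% of changes of 1.2 were recovered among 16424 genes. The word test recovered 10 of 10 planted words in each line.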

Results

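Poly(A) RNA sequencing was carried out on 11 libraries from 2 human pancreatic cancer cell lines, AsPC-1 and PANC-1, with or without small interfering RNA (siRNA) against MYEOV. AsPC-1 had 2 control and 3 MYEOV siRNA libraries, and PANC-1 had 3 of each. RNA of the siRNA libraries was prepared 48 hours after transfection. Total counts on genes were 14456544 and 12127194 in the AsPC-1 controls and 13348793, 13517336 and 13483997 in the AsPC-1 siRNA libraries. In PANC-1 they were 14191470, 12561078 and 14541631 in the controls and 15066456, 12920371 and 12113093 in the siRNA libraries. From 22050 to 24025 genes had at least 1 count. The labels describe the controls both as wild type and as untreated, whereas the protocol also names a negative-control siRNA, so the treatment of the control cells is not settled. If they were untreated, the comparisons do not separate MYEOV siRNA from transfection itself. The protocol names a pair of siRNAs against MYEOV, and whether the numbers of the siRNA libraries mark replicates or siRNAs is not given in the sources used here. Nor do the labels say that libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

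The first question was how far the target itself was lowered, and what happened to SOX9 and HES1, a ductal transcription factor and a Notch effector that are part of the question the study asks about MYEOV. MYEOV (ENSG00000172927, chromosome 11, 69294138 to 69367726, plus strand, GRCh38 annotation) fell in both lines. In AsPC-1 it went from 119 ± 0.10 to 42.8 ± 3.6 TMM-normalised CPM (counts scaled to a common library size; mean ± SD, n = 2 controls and 3 siRNA libraries), which left 35.9% of the control level, with a log2 fold change of -1.48 (SE 0.06; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.95e-16). In PANC-1 it went from 75.2 ± 5.8 to 41.0 ± 2.1 CPM (n = 3 and 3), 54.4% of control, with a log2 fold change of -0.88 (SE 0.07; edgeR adjusted p = 4.19e-06). Every siRNA library lay below every control library of its line. The fall was larger in AsPC-1, by 0.59 on the log2 scale (SE 0.10; edgeR interaction test, adjusted p = 0.00153).

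HES1 fell in AsPC-1, from 33.6 ± 0.55 to 27.2 ± 0.58 CPM (log2 fold change -0.30, SE 0.07; edgeR adjusted p = 0.00156), and was not called in PANC-1 (log2 fold change 0.16, SE 0.10; edgeR adjusted p = 0.39). SOX9 rose in PANC-1, from 189 ± 17 to 232 ± 9.0 CPM (log2 fold change 0.30, SE 0.06; edgeR adjusted p = 0.00966), but the call was lost without PANC-1 siRNA replicate 1 (edgeR adjusted p = 0.0555). In AsPC-1 SOX9 was not called (log2 fold change 0.07, SE 0.05; edgeR adjusted p = 0.326). The difference between lines did not pass the edgeR interaction test for HES1 (0.45, SE 0.13, adjusted p = 0.0553) or for SOX9 (0.22, SE 0.09, adjusted p = 0.185).

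**Figure D1:**
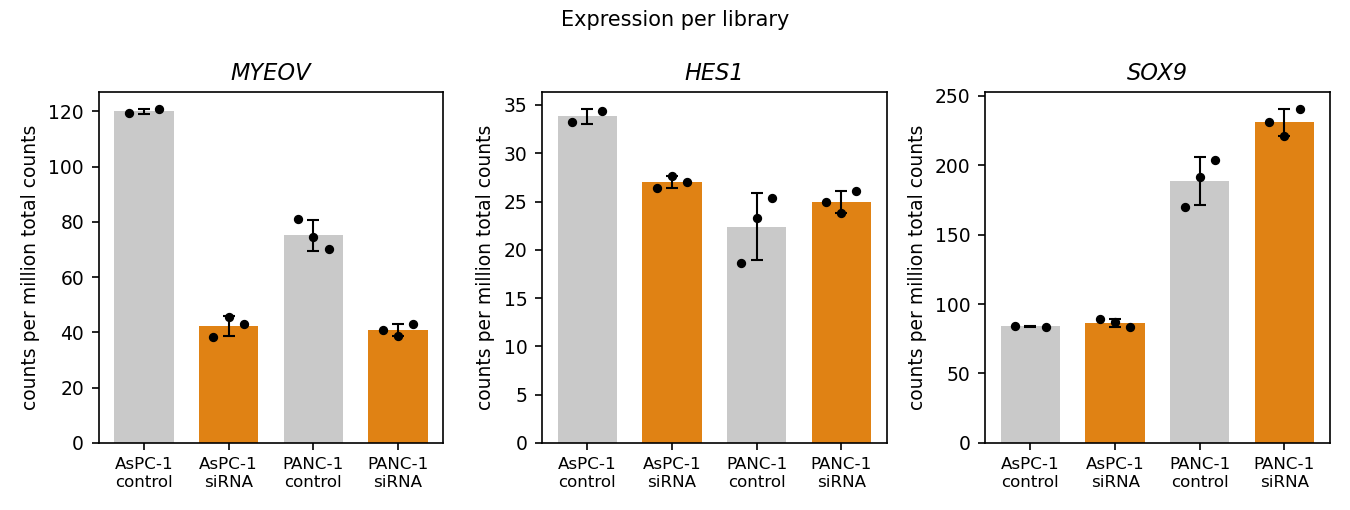
CPM over total counts of MYEOV, HES1 and SOX9 in each library (points), with the group mean (bar, from 0) and SD (error bar) for the 4 groups. MYEOV lay between 38.4 and 45.7 in the AsPC-1 siRNA libraries against 119 and 121 in the controls, and between 38.5 and 43.1 in the PANC-1 siRNA libraries against 70.1 to 81.2 in the controls.

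The second comparison asked which genes responded to MYEOV siRNA in AsPC-1. EMP1, an epithelial membrane protein, had the deepest fall of the genes named here, from 383 ± 5.4 to 95.2 ± 5.3 CPM (n = 2 and 3; log2 fold change -2.01, SE 0.04; edgeR adjusted p = 1.77e-21). MSN, which encodes moesin, a linker of actin to the plasma membrane, fell to 26.5% of control, and ARHGAP1, a GTPase-activating protein, to 28.3%. TMTC3, the lysosomal cholesterol carrier NPC2 and the mRNA export factor ALYREF fell to between 32.6% and 34.3% of control. PLAU, the urokinase plasminogen activator, rose from 23.4 ± 0.17 to 91.5 ± 4.9 CPM (log2 fold change 1.97, SE 0.06; edgeR adjusted p = 1.53e-17).

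TGFB2, a TGF-beta ligand, rose 3.15-fold, RAB5IF 2.73-fold, the complex I assembly factor NDUFAF8 2.70-fold and carbonic anhydrase CA9 2.58-fold. SIK1, a salt-inducible kinase, rose to 399.7% of control but varied between siRNA libraries, with 76, 155 and 267 counts against 37 and 46 in the controls. MSN, ARHGAP1, EMP1, TMTC3, NPC2 and ALYREF all carry the 7-base word CTCATGT in their 3' UTR, a word that 12.8% of the tested genes with an annotated 3' UTR carry. The edgeR test called 4709 of 14304 genes at an adjusted p under 0.05, 2377 higher and 2332 lower in siRNA libraries, of which 101 and 178 changed more than 2-fold. DESeq2 called 2871, 1576 higher and 1295 lower. Among called genes the median absolute log2 fold change was 0.32.

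Ribosomal protein mRNAs rose together in AsPC-1 by small amounts. Of 74 tested, 59 were higher and 0 lower (62 and 1 when adjusted over the list alone), with a median log2 fold change of 0.14. RPS29 (log2 fold change 0.43) and RPS27 (0.30) were among the larger rises. limma's camera test with a preset correlation of 0.01 called the list (adjusted p = 1.87e-15), and the call was lost with the correlation estimated from the data (adjusted p = 0.438 with an estimated correlation). Ribosomal protein genes share sequence with many pseudogenes, so their counts are uncertain. Mitochondrial genes took 13.6 ± 0.55% of counts in the controls and 13.7 ± 0.15% in the siRNA libraries.

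Targets of YAP and TEAD, the transcriptional regulators of the Hippo pathway, were higher as a group in AsPC-1. Of 17 tested, 11 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 9.18e-06, and adjusted p = 0.438 with an estimated correlation). TGFB2 and the receptor tyrosine kinase AXL (73.1 ± 2.5 to 123 ± 2.3 CPM) led the list. ERK pathway output genes were also higher, 11 rising and 3 falling of 19 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0158, and adjusted p = 0.545 with an estimated correlation). The transcription factors ETV5 (log2 fold change 0.93) and FOSL1 (log2 fold change 0.58) rose most among them, while DUSP6, SPRY2 and CCND1, which are induced by the same pathway, fell.

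Genes of G2/M and mitosis fell in AsPC-1, 14 lower and 2 higher of 24 (16 and 2 adjusted over the list alone; camera adjusted p = 3.60e-04, and adjusted p = 0.471 with an estimated correlation). The mitotic kinesin KIF23 fell to 71.8% of control and the anaphase-promoting complex activator CDC20 to 72.9%, whereas MKI67 and ANLN rose. Of 21 glycolysis and hypoxia-response genes, 8 rose and 1, NDRG1, fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0425, and adjusted p = 0.471 with an estimated correlation). CA9 led this list too, and ADM (log2 fold change 0.53) was called in the full data but not without AsPC-1 control replicate 1 (edgeR adjusted p = 0.131), control replicate 2 (0.0507) or siRNA replicate 2 (0.0755).

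Camera called 5 of 25 lists in AsPC-1 and 0 with an estimated correlation, while fry, limma's rotation test, called 12. Of the rest, SOX9 and Notch genes (5 higher and 1 lower of 11, camera adjusted p = 0.0616) came closest. Single members changed within lists that were not called. The integrin subunit ITGB1 fell from 2490 ± 76 to 1161 ± 64 CPM, the apoptosome component APAF1 to 41.3% of control, the cell cycle inhibitor CDKN1A to 49.6%, XBP1 to 69.5% and HNF4A to 68.2%. NOTCH2 rose 1.34-fold, the cystine transporter SLC7A11 1.68-fold, DICER1 1.58-fold, TGFBI 1.42-fold and ANO1, a neighbour of MYEOV at 11q13, 1.70-fold. HSPD1, CLDN4, ISG20, LIF and MT-ND6 also rose, by 1.17-fold to 1.46-fold. LUM, an extracellular matrix proteoglycan on the list of fibroblast markers, fell from 276 ± 6.9 to 95.0 ± 1.5 CPM; only 2 of the 12 fibroblast markers passed the expression filter. Among markers of other cell types LYZ (log2 fold change -0.05) and ENG (0.20) were not called.

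The third comparison asked the same of PANC-1. The deepest falls named here were those of EMP1, from 72.1 ± 5.4 to 26.7 ± 0.53 CPM (n = 3 and 3; log2 fold change -1.43, SE 0.07; edgeR adjusted p = 1.10e-07), NPC2 (38.8% of control), the phosphatase PRUNE1 (40.7%), ALYREF (41.6%), the iron-sulfur assembly factor CIAO2A (42.2%) and DIXDC1, a Wnt pathway protein (43.7%). MAP2K6, the kinase upstream of p38, rose from 6.43 ± 1.4 to 12.3 ± 0.89 CPM (log2 fold change 0.94, SE 0.14; edgeR adjusted p = 0.00121). Haem oxygenase HMOX1 rose 1.74-fold, the actin-bundling protein gene ESPN 1.75-fold, CCDC9B 1.74-fold and the glycosyltransferase B3GNT7 1.68-fold. EMP1, NPC2, PRUNE1, ALYREF and DIXDC1 carry CTCATGT in the 3' UTR, and CIAO2A does not.

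In PANC-1 the edgeR test called 1356 of 14929 genes, 621 higher and 735 lower, of which 11 and 27 changed more than 2-fold. The count depended on single libraries: it was 538 without siRNA replicate 1, 876 without siRNA replicate 2 and 863 without siRNA replicate 3. It was 628 with the replicate number as a block and 1124 with DESeq2. The pseudogene LSM12P1 (log2 fold change 0.85) was called in the full data but not without control replicate 3 (edgeR adjusted p = 0.0739) or siRNA replicate 1 (0.0928).

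Genes of DNA replication and mitosis fell in PANC-1. Of 24 G1/S and replication genes, 8 fell and 0 rose (13 and 1 adjusted over the list alone; camera adjusted p = 1.95e-05, and adjusted p = 0.384 with an estimated correlation), among them the replication factor GINS2 (72.4% of control) and members of the MCM helicase, MCM3 to MCM7. The histone chaperone subunit CHAF1A (81.9%) was not called without siRNA replicate 1 (edgeR adjusted p = 0.0516) or siRNA replicate 3 (0.0531). Of 24 G2/M genes, 8 fell and 1, ANLN, rose (9 and 1 adjusted over the list alone; camera adjusted p = 1.22e-04, and adjusted p = 0.384 with an estimated correlation). The kinesins KIF11 (76.1% of control) and KIF20A (79.1%) fell most among them. Both carry CTCATGT in the 3' UTR, as do 12.9% of the genes with a 3' UTR tested in PANC-1.

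SOX9 and Notch pathway genes rose as a group in PANC-1, 4 of 17 higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 2.34e-04, and adjusted p = 0.283 with an estimated correlation). The called genes were LFNG, a modifier of Notch receptors (1.40-fold), SOX9, the ligand JAG1 and the receptor NOTCH2; SOX9 lost its call without siRNA replicate 1 (edgeR adjusted p = 0.0555). Of 19 ATF4 targets of amino acid stress, 5 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 1.95e-05, and adjusted p = 0.283 with an estimated correlation). SESN2, an inhibitor of mTORC1, rose 1.31-fold. SLC7A11 (1.45-fold) lost its call without control replicate 1 (edgeR adjusted p = 0.117), control replicate 3 (0.125), siRNA replicate 1 (0.0868) or siRNA replicate 3 (0.138). NF-kB inflammatory genes were higher, 5 rising and 1, CXCL1, falling of 17 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0191, and adjusted p = 0.283 with an estimated correlation).

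RNA interference genes fell in PANC-1, 4 of 11 lower and 0 higher (4 and 1 adjusted over the list alone; camera adjusted p = 0.0226, and adjusted p = 0.283 with an estimated correlation). AGO1, an Argonaute protein, fell to 71.3% of control. The other called members were AGO2, PRKRA and TARBP2. All 4 carry TCATGT, the core of CTCATGT, in the 3' UTR, as do 38.9% of the genes with a 3' UTR tested in PANC-1. AGO1, AGO2 and TARBP2 carry 3, 2 and 1 copies of the whole word. AGO3, AGO4 and DICER1, also on the list, carry the whole word too and were not called lower. TARBP2 lost its call without control replicate 1 (edgeR adjusted p = 0.0617), control replicate 3 (0.0536) or siRNA replicate 3 (0.0603). Mitochondrially encoded mRNAs fell, 4 of 13 lower and 0 higher (6 and 0 adjusted over the list alone; camera adjusted p = 4.89e-04, and adjusted p = 0.283 with an estimated correlation), and mitochondrial genes took 6.62 ± 0.17% of counts in the controls and 6.30 ± 0.14% in the siRNA libraries. MT-ND3 (87.1% of control) and MT-CYB (87.5%) lost their calls without siRNA replicate 1 (edgeR adjusted p = 0.0953 and 0.0562).

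Camera called 7 of 26 lists in PANC-1 and 0 with an estimated correlation, while fry called 9. Splits of the PANC-1 libraries that mixed the groups called up to 9 lists with the preset correlation. In lists that were not called, SMAD3, a transducer of TGF-beta signals, fell from 687 ± 15 to 469 ± 6.2 CPM, ITGB1 to 63.9% of control, APAF1 to 55.2% and IRF7 to 64.7%, and the keratin KRT8 fell by 0.41 on the log2 scale. PHGDH, which starts serine synthesis, rose 1.30-fold, GDF15 1.29-fold and EPHA2 1.24-fold. Ribosomal protein mRNAs stood at 0 higher and 0 lower of 74 in PANC-1, with a median log2 fold change of -0.01 (camera adjusted p = 0.661; fry adjusted p = 0.902; 3509 of all tested genes had an unadjusted edgeR p under 0.05).

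The fourth comparison set the lines side by side. EMP1, NPC2, PRUNE1, ALYREF, CIAO2A and BZW2 fell to less than 50% of control in both lines; BZW2, a regulator of translation initiation, went from 200 ± 7.6 to 77.1 ± 1.6 CPM in AsPC-1 and from 128 ± 4.7 to 58.0 ± 2.0 CPM in PANC-1. AKIRIN1, the translation repressor EIF4EBP2, TMEM87B, the RNA-binding protein gene RBMS1, TMEM245 and FAM222B rose in both, by 1.65-fold to 2.26-fold in AsPC-1 and by 1.51-fold to 1.60-fold in PANC-1. Of 12893 genes tested in both lines, 359 rose in both and 512 fell in both, where independent lists would share 100.9 and 115.8. Another 44 changed in opposite directions, against 217.8 for independent lists. The 871 shared changes made up 68.5% of the 1271 PANC-1 calls among these genes, and no library was used in both comparisons. Without PANC-1 siRNA replicate 1 there were 413 shared changes, and 467 with the replicate number as a block. Across genes, which are not independent replicates, log2 fold changes in the lines correlated with Pearson's r = 0.438 and a Spearman rank correlation of 0.428. Pearson's r was 0.046 with no low-count filter, 0.139 in 1 fit over all groups, 0.594 with DESeq2 and 0.624 with a stricter filter.

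**Figure D2:**
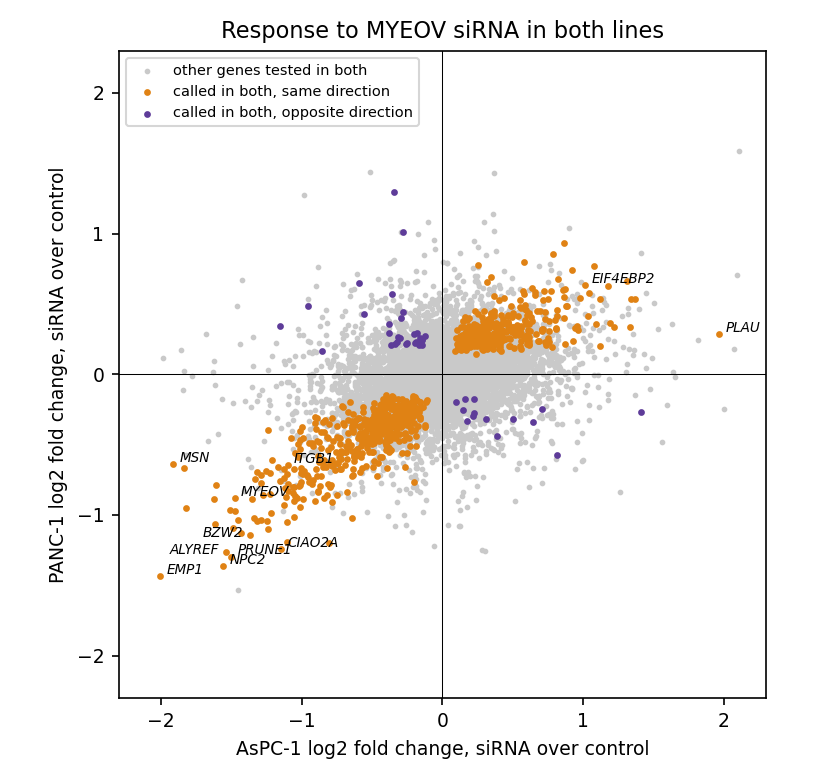
Log2 fold change (siRNA over control) of each gene tested in both lines, AsPC-1 on the horizontal and PANC-1 on the vertical axis, with genes called in both lines coloured by whether they moved the same way (871) or opposite ways (44). Of 12893 genes, 3 lie outside the axes, and EMP1, NPC2, PRUNE1, ALYREF, CIAO2A and BZW2 lie at the lower left.

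Differences between lines were tested directly. PLAU rose more in AsPC-1 (log2 difference, PANC-1 minus AsPC-1, -1.69, SE 0.10; edgeR interaction adjusted p = 1.63e-09), as did TGFB2 (-1.69, SE 0.15; adjusted p = 3.59e-07), RAB5IF (-1.43) and ETV5 (-0.71). MSN fell more in AsPC-1 (1.26, SE 0.08; adjusted p = 1.63e-09), as did ARHGAP1 (0.86), EMP1 (0.56) and ITGB1 (0.44). KRT8 fell and CCDC9B rose more in PANC-1 (-0.42 and 0.78), each past the edgeR interaction test. The test called 727 of 16680 genes, and the response was larger in size in AsPC-1 for 604 of them and in PANC-1 for 123. The fitted fold changes had the same sign in both lines for 327 of these genes and opposite signs for 400, whether or not each was called in its line. The count was 305 without AsPC-1 control replicate 1, 315 without AsPC-1 control replicate 2 475 without PANC-1 siRNA replicate 1 and 241 with the replicate number as a block.

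**Figure D3:**
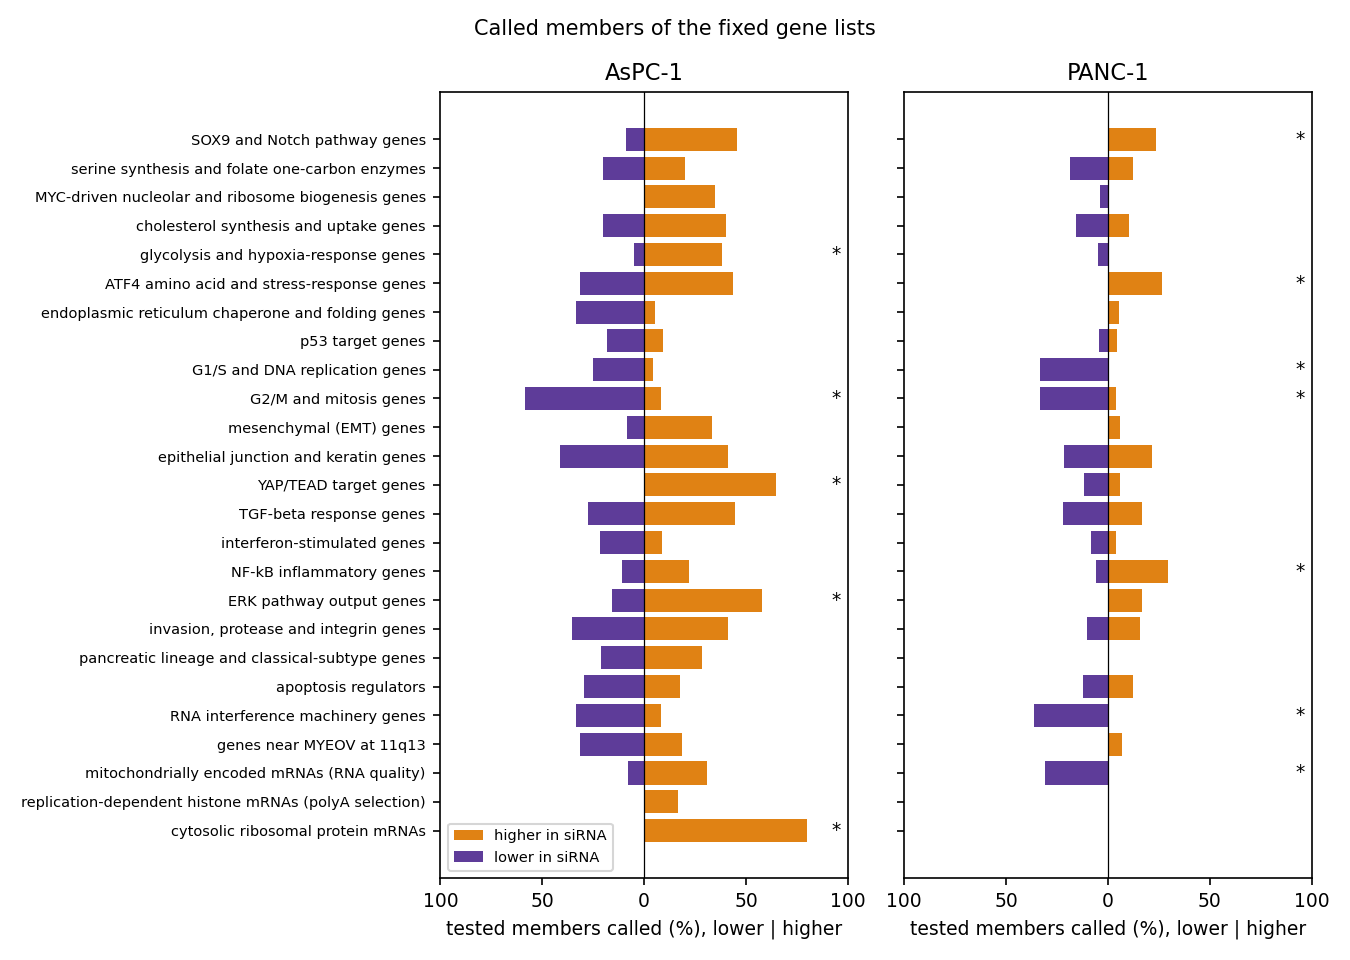
Percentage of tested members called higher (to the right) or lower (to the left) in siRNA libraries, for AsPC-1 and PANC-1. Shown are the fixed gene lists with at least 5 tested members in both lines. A star marks lists called by camera with the preset correlation. Ribosomal protein mRNAs have 59 of 74 members higher in AsPC-1 and 0 in PANC-1.

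Some of these genes overlap an annotated gene on the opposite strand, among them PLAU, CA9, NPC2, ALYREF, BZW2, ITGB1, APAF1, SOX9 and ESPN. Whether the counting used strand is not given in the sources used here, so their values may include antisense reads.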

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

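The test with a spread shared by both lines and the tests of scaling were chosen after their results had been seen; the other tests below were set before their values were computed, after the patterns themselves were noticed.

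The response to MYEOV siRNA differed between the lines for 727 genes in the edgeR interaction test, which is what drew attention here. The counts were 305 without AsPC-1 control replicate 1, 315 without AsPC-1 control replicate 2 475 without PANC-1 siRNA replicate 1 and 241 with the replicate number as a block. MYEOV itself differed by 0.59 on the log2 scale (PANC-1 minus AsPC-1). MAPK8IP2 differed by 1.72, from 53 and 67 counts in AsPC-1 controls to 18, 20 and 12 with siRNA, against 583, 450 and 556 to 536, 449 and 437 in PANC-1. SLC6A9 differed by 1.70, with 25 and 29 counts in AsPC-1 controls and 11, 11 and 4 with siRNA. MYB differed by -2.29: it rose in AsPC-1 from 200 and 204 counts to 383, 416 and 417, while PANC-1 held 8, 13 and 12 counts in controls and 4, 3 and 6 with siRNA.

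For LCA5 and ABO 1 line lies near zero, and the fitted difference depends on the prior count and bounds nothing. LCA5 (-5.25) had 0 and 0 counts in AsPC-1 controls and 6, 5 and 4 with siRNA. ABO (3.76) had 0, 0 and 1 counts in PANC-1 controls and 5, 5 and 1 with siRNA, and in AsPC-1 it fell from 358 and 276 counts to 199, 208 and 170.

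Camera called a difference between lines for 9 lists and for 0 of them with an estimated correlation, where the lowest adjusted p was 0.0741; fry called 8. Relative to AsPC-1, PANC-1 moved down for ribosomal protein mRNAs (adjusted p = 6.15e-21), YAP/TEAD targets (5.53e-08), mitochondrial mRNAs (1.70e-06), MYC-driven ribosome biogenesis genes (5.07e-05), cholesterol genes and TGF-beta response genes (0.00359 each), glycolysis and hypoxia genes (0.0108) and ERK output genes (0.0111). Endoplasmic reticulum chaperones moved up (0.0197).

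More genes were called in AsPC-1 (4709) than in PANC-1 (1356), although AsPC-1 had fewer libraries; DESeq2 called 2871 and 1124. With 1 spread shared by both lines the counts were 3503 and 1975, a ratio of 1.77, so a lower spread in AsPC-1 is not the whole of the difference, though the ratio is far smaller than that of the separate fits. Among genes without the word core TCATGT in the 3' UTR the share called was 33.3% in AsPC-1 and 7.66% in PANC-1, a ratio of 4.34. With the core the shares were 42.4% and 14.4%. The excess in AsPC-1 is thus not confined to genes with the core. These shares come from the separate fits, whose spreads differ, so the ratio cannot decide whether 3' UTR matches of this word are the whole cause. Other seeds and sites in coding sequence were not removed. A difference in knockdown depth or in the lines' biology stays open and was not tested.

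Ribosomal protein mRNAs rose in AsPC-1, with a median log2 fold change of 0.135, and had a median of -0.01 in PANC-1. They are short, so genes matched on length and mean expression were compared: in AsPC-1 these had a median of 0.0552 over 1000 random matched sets, the excess of the ribosomal protein mRNAs was 0.0798, and 0 of 1000 sets reached their median. Part of the rise is thus shared with genes matched in this way. Length was that of the coding sequence plus the longest annotated 3' UTR, which need not be the form expressed. An effect of length on the excess is therefore not excluded. The sets drew genes independently, while the list had an estimated correlation of 0.109 between its genes. So 0 of 1000 does not measure how rare the excess is. Camera with an estimated correlation lost the call of the list (adjusted p = 0.438). But that setting called 0 lists in either line. It also lost NF-kB genes in PANC-1 (camera adjusted p = 0.0191 to 0.283), whose estimated correlation of -0.026 was below the preset 0.01. The loss can therefore not be put down to the correlation between genes alone. A scaling factor moves the matched genes as well, so it does not account for the excess over them; for the rest of the rise scaling cannot be told apart, since RLE and upper-quartile scaling (smallest median 0.136) shifted the median of all genes by 0.0022 at most. Reads shared with pseudogenes were not tested, and a biological response of AsPC-1 cells stays open as a hypothesis.

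In PANC-1, 1 of the 10 splits of the 6 libraries, the real one, called as many genes: 1356, with 1 as the highest of the others. For gene lists, 2 of the 10 splits called as many, the real split with 7 and another with 9 (controls 1 and 2 with siRNA 2 against the rest). The splits that mixed the groups called 6, 9, 1, 0, 5, 2, 2, 3 and 1 lists, although they called at most 1 gene. Each of them stays unbalanced in siRNA libraries, so part of the real contrast remains. A camera call with the preset correlation is thus weak evidence on its own in PANC-1. So few splits give no share under 0.05.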

How the results depend on the processing

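The restriction to genes without the word core was chosen after the results were seen; the other settings were planned. MYEOV kept its direction and call under every planned setting that gave it a value, with log2 fold changes from -1.53 to -1.41 in AsPC-1 and from -0.93 to -0.82 in PANC-1 on leaving out each library in turn; where 1 AsPC-1 control was left, it was assumed to vary like the other groups. RLE and upper-quartile scaling left every main count within 1.5 times.

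DESeq2 called 2871 genes in AsPC-1, and the correlation between lines was 0.594 on its fold changes. The correlation was 0.046 with no low-count filter, 0.139 in 1 fit over all groups and 0.624 with the stricter filter; these settings differ in how many low-count genes enter. With no filter 8 lists were called in AsPC-1. With an estimated correlation camera called 0 lists in AsPC-1 and 0 in PANC-1, and fry called 12 in AsPC-1. Among genes without the core, 2445 genes were called in AsPC-1, 529 in PANC-1 and 343 in the same direction in both, with a correlation of 0.361; fewer genes were tested there.

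Leaving out each library gave 3164 to 4393 genes in AsPC-1, 538 to 1712 in PANC-1 (538 without siRNA replicate 1, 876 without siRNA replicate 2, 863 without siRNA replicate 3), 305 to 1056 for the difference between lines (305 and 315 without AsPC-1 controls 1 and 2, 475 without PANC-1 siRNA replicate 1), 413 to 1042 shared changes (413 without PANC-1 siRNA replicate 1), a correlation of 0.381 to 0.435, 4 to 7 lists in AsPC-1 and 6 to 8 in PANC-1. In PANC-1, genes that were never called changed sign: ENG ran from -0.0793 to 0.0301, RN7SL2 from -0.10 to 0.32 and CD14 from -0.51 to 0.15. Over all settings, named genes gave 1393 values with direction and call kept, 59 with the call lost, 9 with a call gained and 6 reversed. The cause of these changes was not tested. Of the named calls, 3 of 55 in AsPC-1 and 16 of 50 in PANC-1 were lost on leaving out some library.

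With the replicate number as a block, 628 genes were called in PANC-1, 241 for the difference between lines and 467 in both lines. Same-numbered libraries did not deviate together (correlations of -0.03 and 0.01 in AsPC-1, and of -0.01, -0.40 and -0.10 in PANC-1), and no PANC-1 control correlated best with the siRNA library of its own number. The highest PANC-1 correlations were 0.38, of control 1 with siRNA 2 and of control 2 with siRNA 3. Deviations from means of so few libraries mirror each other. These values therefore show no sign of pairing by number but cannot exclude it. At this depth, simulated changes of 0.3 on the log2 scale were recovered for 68.7% of the changed genes in AsPC-1 and 40.3% in PANC-1. These genes had a mean log2 CPM above 3 and no spread of their own beyond the trend, so recovery among all tested genes may be lower. Depth was not varied.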

Other observations

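The test of control siRNA behind the rising word and the test of the word's weakest z in a single library were chosen after their results were seen; the other tests below were set before their values were computed, after a word shared by falling genes was looked for.

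Gene lists that camera did not call are given here by their counts, each with the count adjusted over the list alone and the camera adjusted p. In AsPC-1, the edgeR test called higher and lower 5 and 1 of 11 SOX9 and Notch genes (list alone 6 and 2, adjusted p = 0.0616), 3 and 3 of 15 serine and folate enzymes (list alone 4 and 3, adjusted p = 0.923), 9 and 0 of 26 MYC-driven ribosome biogenesis genes (list alone 9 and 0, adjusted p = 0.14) and 8 and 4 of 20 cholesterol genes (list alone 8 and 4, adjusted p = 0.321). Called higher and lower were also 7 and 5 of 16 ATF4 targets (list alone 7 and 5, adjusted p = 0.403), 1 and 6 of 18 endoplasmic reticulum chaperones (list alone 1 and 6, adjusted p = 0.321), 2 and 4 of 22 p53 targets (list alone 2 and 4, adjusted p = 0.638) and 1 and 6 of 24 G1/S genes (list alone 1 and 6, adjusted p = 0.124). The counts were 4 and 1 of 12 mesenchymal genes (list alone 4 and 2, adjusted p = 0.533), 7 and 7 of 17 epithelial genes (list alone 7 and 7, adjusted p = 0.923), 8 and 5 of 18 TGF-beta response genes (list alone 9 and 6, adjusted p = 0.638) and 2 and 5 of 23 interferon-stimulated genes (list alone 2 and 5, adjusted p = 0.923). There were 4 and 2 of 18 NF-kB genes (list alone 4 and 2, adjusted p = 0.923), 7 and 6 of 17 invasion and matrix genes (list alone 8 and 6, adjusted p = 0.881), 4 and 3 of 14 pancreatic lineage genes (list alone 5 and 4, adjusted p = 0.923) and 3 and 5 of 17 apoptosis regulators (list alone 4 and 5, adjusted p = 0.543). Next came 1 and 4 of 12 RNA interference genes (list alone 1 and 4, adjusted p = 0.311), 3 and 5 of 16 neighbours of MYEOV at 11q13 (list alone 4 and 5, adjusted p = 0.881), 4 and 1 of 13 mitochondrial mRNAs (list alone 4 and 1, adjusted p = 0.543) and 1 and 0 of 6 histone mRNAs (list alone 1 and 0, adjusted p = 0.638). For mesenchymal genes in AsPC-1 the median log2 fold change was -0.04 while the mean and the test pointed up, for invasion and matrix genes the median was -0.05 while the mean and the test pointed up, and for NF-kB genes the median and mean were -0.07 and -0.12 while the test pointed up. Epithelial genes in AsPC-1 had a median of -0.007 and a mean of -0.032 while the test pointed up. Serine and folate enzymes in AsPC-1 had a median of 0.027 and a mean of -0.021 while the test pointed up.

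In PANC-1, the edgeR test called higher and lower 2 and 3 of 16 serine and folate enzymes (list alone 3 and 4, adjusted p = 0.679), 0 and 1 of 26 MYC-driven ribosome biogenesis genes (list alone 0 and 0, adjusted p = 0.0994), 2 and 3 of 19 cholesterol genes (list alone 3 and 4, adjusted p = 0.236) and 0 and 1 of 21 glycolysis and hypoxia genes (list alone 0 and 1, adjusted p = 0.438). Called higher and lower were also 1 and 0 of 18 endoplasmic reticulum chaperones (list alone 0 and 0, adjusted p = 0.373), 1 and 1 of 23 p53 targets (list alone 3 and 1, adjusted p = 0.472), 1 and 0 of 17 mesenchymal genes (list alone 1 and 0, adjusted p = 0.313) and 3 and 3 of 14 epithelial genes (list alone 5 and 3, adjusted p = 0.601). The counts were 1 and 2 of 17 YAP/TEAD targets (list alone 2 and 2, adjusted p = 0.472), 3 and 4 of 18 TGF-beta response genes (list alone 4 and 5, adjusted p = 0.236), 1 and 2 of 24 interferon-stimulated genes (list alone 2 and 2, adjusted p = 0.894) and 3 and 0 of 18 ERK output genes (list alone 5 and 3, adjusted p = 0.438). There were 3 and 2 of 19 invasion and matrix genes (list alone 3 and 2, adjusted p = 0.228), 0 and 0 of 10 pancreatic lineage genes (list alone 0 and 0, adjusted p = 0.894), 2 and 2 of 16 apoptosis regulators (list alone 2 and 2, adjusted p = 0.894) and 1 and 0 of 15 neighbours of MYEOV at 11q13 (list alone 1 and 0, adjusted p = 0.438). Next came 1 and 0 of 5 fibroblast markers (list alone 2 and 0, adjusted p = 0.225) and 0 and 0 of 6 histone mRNAs (list alone 1 and 0, adjusted p = 0.476). For apoptosis regulators in PANC-1 the median log2 fold change was 0.02 and the mean -0.01. CYP51A1, a sterol demethylase of the cholesterol list, fell to 46.0% of control in AsPC-1 and 57.1% in PANC-1, and was named after its values were seen. Its 3' UTR holds 2 copies of CTCATGT. Of leukocyte markers 2 of 12 passed the expression filter in AsPC-1 and 1 in PANC-1, of endothelial markers 1 of 8 in each line, of fibroblast markers 2 of 12 in AsPC-1, and of non-polyadenylated RNAs 1 of 5 in each, too few to test as lists.

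Carriers of a 7-base word in the 3' UTR had lower fold changes than other genes in each line. Of 16384 words, CTCATGT had the lowest rank statistic in each line, z = -16.39 in AsPC-1 and -18.85 in PANC-1, where 100 permutations reached -4.92 and -4.89. Of genes with an annotated 3' UTR that were lowered in AsPC-1, 556 of 2120 (26.2%) carried it, and of those lowered in PANC-1, 315 of 688 (45.8%), against 12.8% and 12.9% of all genes tested with a 3' UTR. Among those lowered more than 2-fold, again with an annotated 3' UTR, 68 of 133 in AsPC-1 and 18 of 23 in PANC-1 carried it. Genes with the 8-base site CTCATGTA had median log2 fold changes of -0.21 and -0.16, and 194 of 389 (49.9%) and 122 of 400 (30.5%) fell, whereas genes without the core TCATGT had medians of 0.03 and 0.02, with 13.04% and 2.39% falling. The reverse complement, ACATGAG, gave z values of 1.11 and 0.93.

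The named genes given next are not a complete list, so they give no share of carriers. EMP1, NPC2, PRUNE1, ALYREF, BZW2, ITGB1, APAF1, XBP1, CDKN1A, HNF4A, SMAD3, KIF11, KIF20A and CYP51A1 fell and carry the word. LUM, KIF23 and CDC20 fell without the whole word but carry its core TCATGT. HES1, MAPK8IP2, ABO, CIAO2A, GINS2, CHAF1A, KRT8 and IRF7 fell without the core. TMEM245 rose in both lines and DICER1 in AsPC-1 although they carry the whole word. When only genes with an annotated 3' UTR and without the core were tested, camera with the preset correlation still called ribosomal protein mRNAs (adjusted p = 2.18e-10), YAP/TEAD targets (9.54e-04) and hypoxia genes (0.00658) upward and G2/M genes (0.0331) downward in AsPC-1. In PANC-1 it still called ATF4 targets (adjusted p = 9.35e-04), SOX9 and Notch genes (0.00328) and NF-kB genes (0.042) upward and G1/S genes (3.60e-07) downward. Cholesterol genes (camera adjusted p = 0.0108, upward) and G1/S genes (0.0331, downward) in AsPC-1 and MYC-driven ribosome biogenesis genes (0.0168, downward) in PANC-1 were called there alone. ERK output genes in AsPC-1 (camera adjusted p = 0.0659, 11 of 19 members left) and G2/M genes in PANC-1 (0.0545, 15 of 24 left) were no longer called. Their directions were unchanged, so the loss alone does not show that the change went with the core. RNA interference genes had too few members left to test. Mitochondrial genes have no annotated 3' UTR and dropped out for that reason. With an estimated correlation camera called 0 lists in either line among genes without the core (lowest adjusted p = 0.359 in AsPC-1 and 0.478 in PANC-1).

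A candidate explanation is that an siRNA against MYEOV lowered other mRNAs through its seed, the bases of the guide that pair with 3' UTRs; the weaker z of the lines, -16.39, lay beyond all permutations, and 7 of 12 annotated MYEOV transcripts hold the word, although 67 of the 420 words with the same bases also occur in MYEOV. The length and base composition of 3' UTRs are argued against, since the word's coefficient kept at least 113.6% of its size after correction for both. The word was also the lowest of the 420, but a word that is the lowest of all words must be. That rank is therefore no evidence. Whether carriers fall for a reason outside the 3' UTR cannot be told apart fully: genes with the word in the coding sequence alone shifted by -0.0677 in AsPC-1 and -0.0328 in PANC-1, against -0.124 and -0.0957 with it in the 3' UTR. The word was the lowest in 5 of the 6 siRNA libraries. In PANC-1 siRNA replicate 2 TCATGTA, shifted by 1 base, was lower (z -19.74 against -19.42). So the test set beforehand, which asked for 6, was not met. But the weakest z of the word in any single siRNA library was -14.64, beyond all permutations. That argues against a different siRNA in each numbered library. The word was also the lowest of the 420 in each library, which follows by itself wherever it was the lowest of all words. The siRNA sequences were not used here, and an effect of MYEOV loss on the same genes was not tested.

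Shared 3' UTR matches of this word were also tested as the source of the fold changes common to the lines. Among genes without the core the correlation was 0.361, against 0.49 among all genes with a 3' UTR, and with the core it was 0.618. Of 491 genes with a 3' UTR that fell in both lines, 388 have the core and 103 do not. Of all 11177 genes with a 3' UTR tested in both lines, 4366 have the core. The core thus goes with most shared falls, but how many of these hold the whole word was not counted. Matches of the core are not the whole of what the lines share. Because the treatment of the controls is not settled, a response of both lines to transfection itself cannot be told apart either. Other seeds and sites in coding sequence were not removed.

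The word whose carriers rose most in AsPC-1 was GTACATT (z = 9.63, permutations up to 5.37). It kept 113.5% of its coefficient after correction for 3' UTR length and base composition. An siRNA given to the controls of both lines could leave such a trace, and this cannot be told apart here. In PANC-1 its z was 2.254, within the permutations, which reached 4.61, but these do not allow for base composition: the GC-rich word CCCACCC had a z of 9.375 there. After correction for length and composition the coefficient was 0.0175 (SE 0.0065, t = 2.71) in PANC-1, against 0.0925 (SE 0.0098) in AsPC-1. Uncorrected it was 0.0079 (SE 0.0060) in PANC-1, so the 220.4% kept says little. The z in PANC-1 ranked 4 from the top among the 420 words with the same bases. For CTCATGT the corrected coefficients were -0.1555 in PANC-1 and -0.1978 in AsPC-1.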
